A study of Mus musculus with 2 samples.

How the data were processed

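The series holds 2 single-cell RNA-seq libraries of cells from injured tibialis anterior muscle of mice, 1 from wild-type (WT) animals and 1 from the conditional Setdb1 knockout (KO). Per the labels' protocols, the muscle was digested with collagenase II and dispase, cells stained with Hoechst and propidium iodide were sorted, and libraries were made with the 10x Genomics single-cell 3' v2 chemistry. The number of animals behind each library, the injury, the day after it and the Cre driver are not given in the sources used here. Per the values in them, the deposited matrices hold whole-number UMI counts (unique molecular identifiers, which count each captured RNA molecule once) per gene and barcode, with no normalization by the authors and no filter on cells. They list 55487 genes for 2821644 WT and 3331422 KO barcodes, with 121703522 and 138667420 UMIs. The submitters' processing notes name STARsolo 2.7.9a, STAR 2.7.8a, Seurat 4.0.1 and the genome build GRCm38. The annotation release and the counting settings are not given in the sources used here.

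Since the matrices hold every barcode, cells were called again. In each library a cell needed at least the 99th percentile of UMIs among the top 3000 barcodes divided by 10, which came to 5145 UMIs in the WT and 6297 in the KO library. It also needed at least 500 UMIs, 300 genes and a mitochondrial share of at most 10%. This left 6670 WT and 6020 KO barcodes. Doublets were scored with Scrublet in scanpy 1.11.5. Its own threshold marked 0 barcodes in both libraries, so the highest scores were removed at 0.8% per 1000 called barcodes, a rule chosen after that outcome was seen. It removed 356 WT barcodes (5.34%) and 290 KO barcodes (4.82%). Ambient RNA, the free RNA that reaches every droplet, was taken from the 23470 WT and 29478 KO barcodes with 20 to 100 UMIs. Barcodes just above that range, such as 33260 WT and 21517 KO barcodes between 126 and 158 UMIs, were not used for it.

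Counts of both libraries were scaled to 10000 UMIs per cell, log-transformed, and reduced to 2000 variable genes chosen within each library and merged. They were then clustered together from 30 components and 15 neighbours at a Leiden resolution of 1 (leidenalg 0.10.2), with no integration. Clusters were named from marker lists of 14 cell classes fixed before the data were examined. The scoring rule was chosen afterwards. Leading genes were the top 10 by fold among genes detected in at least 25% of a cluster's cells. A cluster took the class with the largest share of its markers that were detected in at least 10% of its cells and were higher than in other cells. It stayed unnamed with under 3 such markers, with more markers of another class than of its own among the top 10, or with a median depth under the library's median divided by 3 and no own marker among the top 10. Names ending in "like" carry this meaning.

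UMIs were summed per class and library and given as CPM (a gene's UMIs scaled to the total of its sum). With 1 library per group no test across animals exists, so no p-values were computed. Exact Poisson intervals stand beside CPM, exact Clopper-Pearson intervals beside shares, and conditional binomial intervals beside ratios, all at 95%. The last are exact for ratios of CPM. For ratios of shares they treat numbers of cells as Poisson counts, so they are approximate there and too wide for large shares. All these intervals cover counting error only. Gene-level values are given for classes with at least 50 cells in each library. Log2 ratios of genes and lists used CPM + 5.

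In every such class, genes with at least 50 CPM in 1 library and at least 20 UMIs in both sums together were ranked by the bound of the ratio's interval nearest to 1. The 12 highest and 12 lowest are named in myogenic-like and mononuclear phagocyte-like cells, and the 5 highest and 5 lowest elsewhere. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, Y-linked and Xist genes, and gene models known only by a Gm number or a Rik ending, were left out of the ranking. Up to 4 members of each of 28 gene lists, all fixed before the data were examined, were also open to naming. Other genes named, such as the core members of a list, were chosen after their values were seen. For each list with at least 5 members of 20 UMIs, the median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Genes under 2 times the level that ambient RNA of the same library could give were marked. That level rests on the smallest ratio, over the markers of other classes, of a class's counts to those of pure ambient RNA. For shares of cells with a UMI of a gene, every cell was thinned at random to 1000 UMIs. Of the listed gene identifiers, 55227 were found in the GENCODE release M21 annotation of GRCm38, from which coordinates were taken.

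The intervals and list percentiles were tested on simulated Poisson counts, drawn from the pooled class sums, in which 200 genes had known folds. Such counts follow the model behind the intervals and hold no spread between cells, so they check the calculation only. Cell calling, doublet removal, clustering and naming were not simulated. In the myogenic-like sums (13569 genes), 95.8% of the intervals of unchanged genes held the true ratio, and 76% of genes raised 1.5 times and 98% of those raised 2 times had an interval on the right side of 1. For genes lowered to a ratio of 0.5 that share was 76%. In the phagocyte-like sums (15125 genes) the corresponding shares were 95.4%, 80%, 98% and 94%. Of random lists, 92.5% and 97.5% fell between the 2.5th and 97.5th percentiles.

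Alternatives fixed in advance covered the UMI minimum (500 or 2000 in both libraries), the mitochondrial share (5% or 25%), doublets kept, Leiden resolutions of 0.5 and 2, naming each cell by its own markers, median-ratio scaling, totals without mitochondrial and ribosomal protein genes, each cell weighted equally, 5% ambient RNA subtracted, a pseudocount of 20 CPM, list members with 5 or 100 UMIs, and thinning to 500, to 2000 or not at all. Added after the data were seen were the higher of the 2 UMI minimums in both libraries, clusters built without 126 interferon-stimulated and named genes, use of the largest myogenic-like cluster alone, and the minimum of 2000 UMIs for the shares of myogenic-like cells with a UMI of a gene. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.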

Results

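Cells of injured tibialis anterior muscle were profiled by single-cell RNA-seq from WT mice and from mice with a conditional knockout of Setdb1, the histone methyltransferase that deposits repressive trimethylation on lysine 9 of histone H3. The series title places the question in muscle stem cells during regeneration. Each group had 1 library. The WT library held 121703522 UMIs and the KO library 138667420, and 6314 WT and 5730 KO cells passed the filters, with medians of 12122.5 and 13015.5 UMIs and 2960.5 and 3200.5 genes per cell. Xist gave 3 and 1 UMIs in all WT and KO cells, and the Y-linked gene Ddx3y 38.2 and 49.5 CPM. With 1 library per group no difference given here has a replicate check. Each compares these libraries, and the intervals in brackets (95%) cover counting error only.

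Setdb1 was lower in the KO library in myogenic-like cells, the class that holds muscle stem cells and their progeny. Its level there was 18.2 CPM [16.03 to 20.7] in the WT and 8.85 CPM [7.003 to 11.0] in the KO library, a KO/WT ratio of 0.485 [0.371 to 0.627] from 245 and 79 UMIs. In mononuclear phagocyte-like cells it was higher in the KO library, at 16.7 and 21.7 CPM (ratio 1.30 [1.17 to 1.44]), and in fibro-adipogenic or fibroblast-like cells at 13.9 and 17.3 CPM (1.24 [1.06 to 1.46]). Endothelial-like cells held 11.6 and 11.9 CPM (1.03 [0.754 to 1.40]), and tenocyte-like cells 26 UMIs in each library (0.629 [0.351 to 1.13]). Over all cells the levels were 15.5 and 17.4 CPM (1.12 [1.04 to 1.204]). The 3' tags of this chemistry count only the end of a transcript, and the deleted part of the gene is not given in the sources used here, so that remaining tags need not come from an intact transcript.

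**Figure D1:**
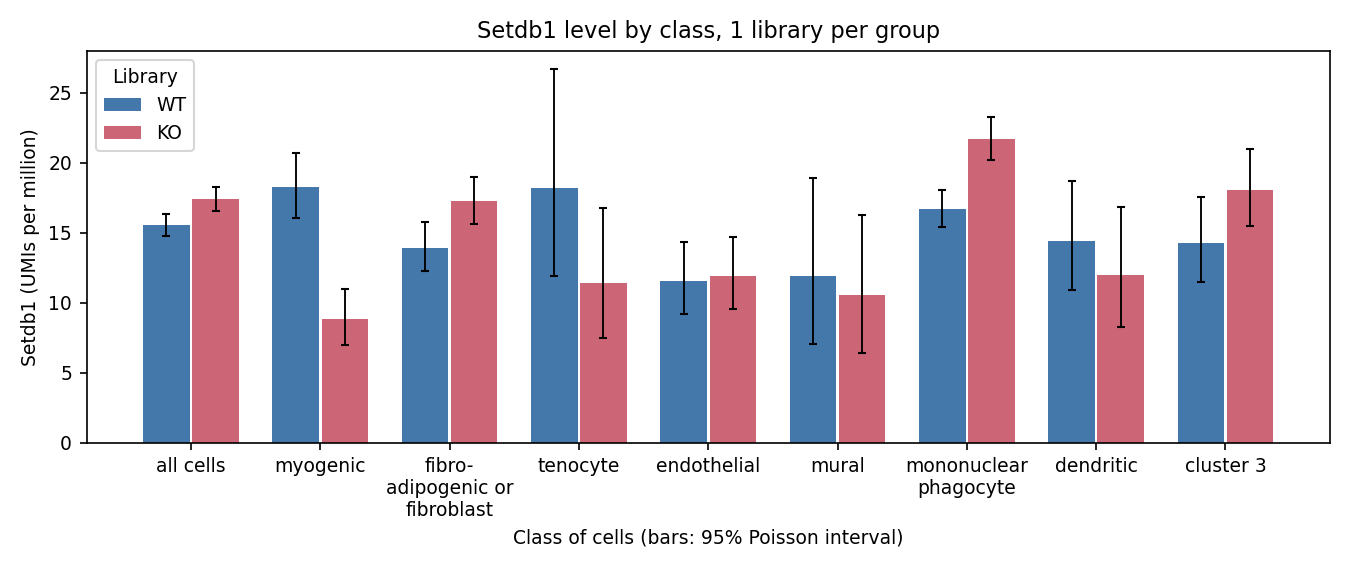
Setdb1 level in CPM (y axis) in each cell class (x axis) of the WT and KO libraries, with exact 95% Poisson intervals as error bars. In myogenic-like cells the KO value of 8.85 lies under the WT value of 18.2, while in mononuclear phagocyte-like cells the KO value of 21.7 lies above the WT value of 16.7.

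Mononuclear phagocyte-like cells, the macrophages and monocytes that clear and remodel injured muscle, were the largest class in both libraries, with 48.0% of the WT cells (3028) and 47.7% of the KO cells (2736). Myogenic-like cells made up 10.8% [10.0 to 11.6] of the WT and 6.56% [5.93 to 7.23] of the KO cells (682 and 376, ratio 0.608 [0.534 to 0.690]). Fibro-adipogenic or fibroblast-like cells, the matrix-producing mesenchymal cells of muscle, made up 12.2% and 13.9% (1.14 [1.03 to 1.26]). Tenocyte-like cells made up 1.31% and 1.94% (1.47 [1.10 to 1.98]), and dendritic-like cells 6.26% and 4.29% (0.686 [0.583 to 0.807]). Endothelial-like cells held 10.5% and 9.91%, mural-like cells (pericytes and smooth muscle) 1.93% and 2.18%, T or NK lymphocyte-like cells 0.824% and 0.541%, and Schwann or glial-like cells 0.507% and 0.454%. The clusters kept out of every class held 7.71% and 12.4% (1.61 [1.44 to 1.81]). These were cluster 3, led by Cxcl2, Il1rn and Clec4e (460 WT and 678 KO cells, with 44 of the 52 phagocyte markers detected), and cluster 25, led by the muscle fibre genes Tnnc2 and Ckm (27 and 35). The naming rule that set cluster 3 apart was chosen after the data were seen.

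These shares stood beside a sort on Hoechst and propidium iodide and beside UMI minimums of 5145 in the WT and 6297 in the KO library. With the higher of these minimums in both libraries, chosen after the data were seen, the myogenic-like share was 11.4% and 6.56% (ratio 0.577 [0.507 to 0.655]). A minimum of 500 UMIs in both libraries gave 9.72% and 7.32% (0.753 [0.688 to 0.825]). With a minimum of 2000 UMIs in both libraries it was 9.37% and 9.89% (1.06 [0.958 to 1.16]), a ratio on the other side of 1 whose interval holds 1. The share of the unnamed clusters was 9.88% and 9.62% with that minimum of 2000 UMIs. The fibro-adipogenic or fibroblast-like share was then 10.7% and 22.4% (2.10) and the tenocyte-like share 1.08% and 2.92% (2.69). Naming each cell by its own markers in place of clusters gave a phagocyte-like share of 15.05% and 15.1%. It also put 14.7% and 20.6% of the cells in the platelet or megakaryocyte class and 9.17% and 13.2% in the neutrophil class. Neither class held cells under the main naming. The minimum of 2000 UMIs gave a phagocyte-like share of 43.1% and 33.6% (0.780 [0.744 to 0.819]).

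**Figure D2:**
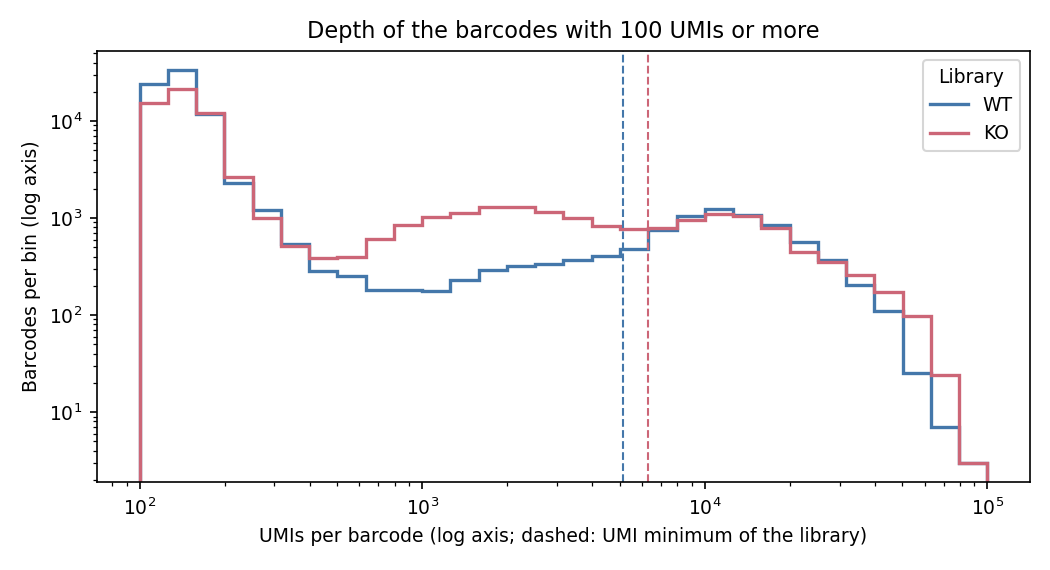
Number of barcodes (y axis) by UMIs per barcode (x axis, log scale) in the WT and KO libraries, with the UMI minimum of each library as a vertical line. Below these minimums of 5145 (WT) and 6297 UMIs (KO) lay 2175 WT and 9392 KO barcodes that had at least 500 UMIs and 300 genes and were left by the mitochondrial filter and the removal of doublets.

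**Figure D3:**
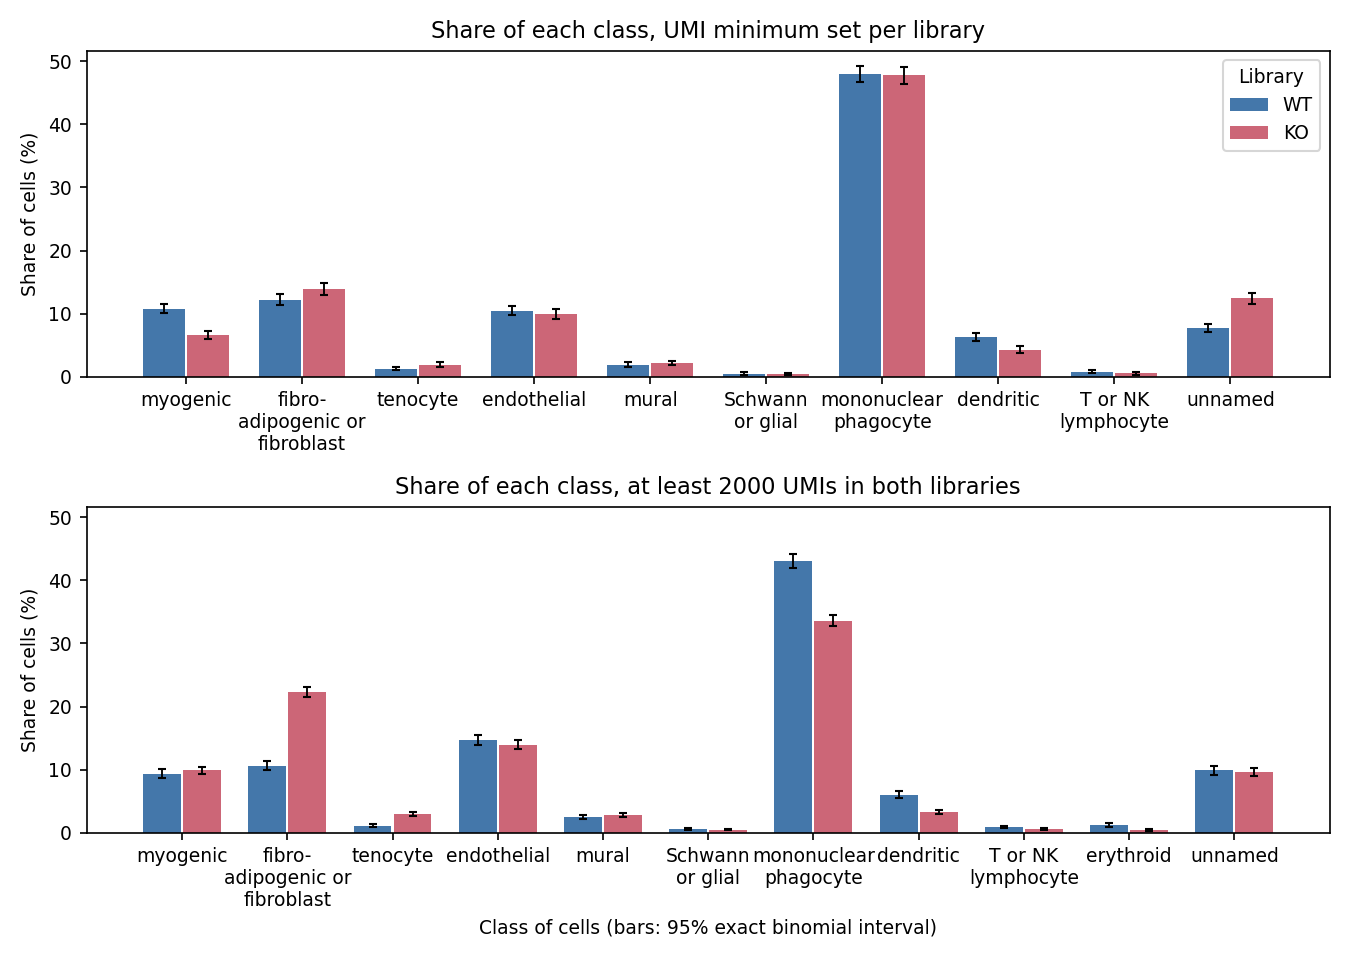
Share of called cells in percent (y axis) per cell class (x axis) in the WT and KO libraries with exact 95% binomial intervals, for the main UMI minimums and for a minimum of 2000 UMIs in both libraries. The myogenic-like share is 10.8% and 6.56% under the former and 9.37% and 9.89% under the latter.

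Within the myogenic-like cells above the main UMI minimums, genes of muscle stem cells were seen in fewer KO than WT cells, and genes of differentiating and cycling cells in more. With every cell thinned to 1000 UMIs, Pax7, the transcription factor of muscle stem cells, had a UMI in 15.8% [13.2 to 18.8] of the WT and 9.31% [6.57 to 12.7] of the KO cells, and Myf5 in 13.8% and 7.71%. Myod1, which drives commitment to muscle, was seen in 6.01% [4.35 to 8.07] and 11.2% [8.17 to 14.8], and Myog, a regulator of terminal differentiation, in 8.21% [6.26 to 10.5] and 21.3% [17.2 to 25.8]. The fusion gene Mymk was seen in 4.25% and 7.18%, a ratio whose interval of 0.962 to 2.96 holds 1, and skeletal actin Acta1 in 7.33% and 13.03%. The proliferation genes Mki67 and Top2a were seen in 6.16% and 13.03%, and in 5.87% and 13.6%. Without thinning, Pax7 stood at 79.0% and 62.0%, Myf5 at 77.9% and 62.0%, Myod1 at 27.7% and 60.1%, Myog at 18.8% and 43.1%, Mymk at 18.0% and 31.9%, Acta1 at 32.0% and 44.7%, Mki67 at 26.5% and 39.9%, and Top2a at 28.0% and 46.5%. Phagocyte-like cells, thinned in the same way, gave a background of 0.0661% and 0.0731% for Pax7, 0.231% and 0.219% for Myog, and 1.35% and 0.987% for Acta1. Their Mki67 share was 1.78% and 2.52%. It is no pure background, since these cells include a cycling cluster with Mki67 and Top2a among its leading genes. The median depth of the myogenic-like cells was 17391.5 and 21105 UMIs and that of the phagocyte-like cells 11218 and 12049.5. Cdkn1a, at 16.3% and 22.9%, lay below its phagocyte-like share of 20.7% and 27.4%, and without thinning the shares were 67.6% and 84.8% in myogenic-like and 67.4% and 74.8% in phagocyte-like cells, which therefore give no background for this gene. Thinned to 500 UMIs, the log2 ratio of the share was -1.59 for Myf5 (-0.84 at 1000 UMIs) and 0.44 for Mki67 (1.08), and the intervals of the ratio held 1 for Pax7 (0.414 to 1.19), Myod1 (0.672 to 2.62), Mymk (0.814 to 3.25), Mki67 (0.696 to 2.61) and Cdkn1a (0.994 to 2.24). Those of Myf5, Myog, Acta1 and Top2a (1.57 to 4.65) did not hold 1. Thinned to 2000 UMIs, the interval of every gene lay apart from 1, with Mymk at 6.16% and 13.8% (2.25 [1.47 to 3.46]). With a minimum of 2000 UMIs in both libraries, chosen for this panel after the data were seen, 710 WT and 1031 KO myogenic-like cells thinned to 1000 UMIs gave Pax7 at 11.97% and 5.82%, Myog at 8.31% and 22.5%, Myod1 at 6.197% and 8.63% (ratio 1.39 [0.960 to 2.05]) and Mki67 at 7.18% and 8.73% (1.22 [0.853 to 1.75]).

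**Figure D4:**
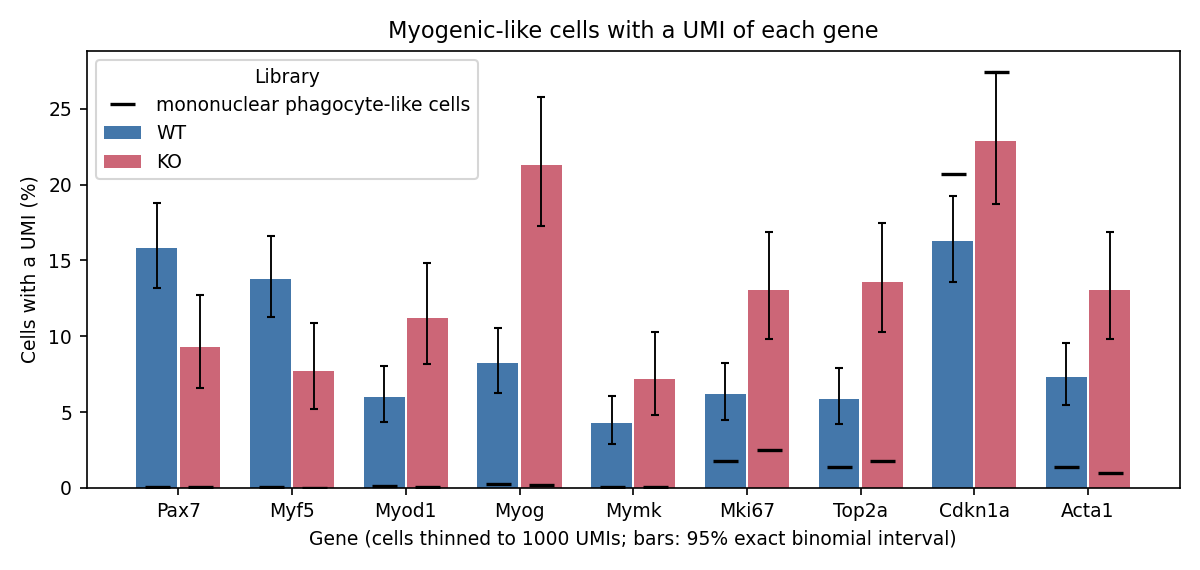
Percent of myogenic-like cells with a UMI of each gene (x axis), every cell thinned to 1000 UMIs, in the WT (682 cells) and KO (376 cells) libraries with exact 95% binomial intervals, and short black ticks for the same share in phagocyte-like cells. Pax7 and Myf5 are lower and Myod1 and Myog higher in the KO library.

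Clusters within the myogenic-like cells, built without the interferon-stimulated and named genes, divided them in a similar way. Pax7, Myf5, Myog, Mymk and Top2a were not among the genes left out, so these clusters are no separate check of the shares above. A cluster led by Cdh15, Myf5 and Pax7 held 85.8% of the WT and 63.0% of the KO myogenic-like cells (585 and 237, ratio 0.735 [0.629 to 0.856]). A cluster led by histone genes and Top2a held 8.21% and 20.2% (2.46 [1.72 to 3.54]), and a cluster led by Actc1, Myog and Mymk held 6.01% and 16.8% (2.79 [1.85 to 4.24]). At a resolution of 2, with all genes used, a cluster led by Pax7, Myf5, Peg3 and Cdh15 held 56.5% and 13.8% (0.245 [0.180 to 0.328]), and one led by Gsta4, Chrna1 and Des, with Cdh15, Peg3 and Mest also among its leading genes, held 31.2% and 51.9% (1.66 [1.36 to 2.03]). Gsta4 and Mest are also among the genes that differed between the libraries.

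In the summed counts of myogenic-like cells, the genes furthest above the WT library included 2 glutathione transferases and 2 partners in retroelement silencing. Cck, a peptide hormone better known from gut and brain, stood at 3.13 CPM in the WT and 527 CPM in the KO library (ratio 169 [125 to 234]), with UMIs in 62 KO cells. Gsta4 stood at 5.36 and 503 CPM (93.8 [74.4 to 120]) and Gstt1 at 12.2 and 100.1 CPM (8.20), both enzymes that conjugate glutathione. Resf1, a retroelement silencing factor, stood at 112 and 739 CPM (6.57 [6.21 to 6.96]), and Atf7ip, the binding partner that stabilises Setdb1, at 32.2 and 119.7 CPM (3.71 [3.32 to 4.16]). Crlf2, a subunit of the receptor for thymic stromal lymphopoietin, stood at 15.04 and 90.4 CPM, the neuronal tubulin gene Tubb3 at 20.5 and 119.7 CPM, Ecrg4 at 11.0 and 150.1 CPM, and the membrane protein gene Tmem52 at 0.149 and 59.5 CPM. Fkbp11, a prolyl isomerase of the secretory pathway, Prkg2, a cGMP-dependent kinase, and Abhd8 completed the 12 highest, with ratios of 4.75, 3.89 and 3.87. Within the largest myogenic-like cluster alone, Cck stood at 3.63 and 47.1 CPM.

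The gene furthest below the WT library was AC160336.1, a long intergenic noncoding RNA (ENSMUSG00000115801, chromosome 14, 44544055 to 44637201, minus strand, GRCm38), at 399.6 and 5.60 CPM (ratio 0.0140 [0.0104 to 0.0185]). Gpc3, a cell-surface heparan sulphate proteoglycan, stood at 63.1 and 6.27 CPM (0.0993 [0.0744 to 0.130]), and Dcx, a microtubule-binding protein of young neurons, at 54.1 and 13.3 CPM (0.247). The lysophosphatidic acid receptor Lpar4 stood at 64.2 and 16.7 CPM, the growth factor Hbegf at 86.9 and 23.7 CPM, the xylosyltransferase Gxylt2 at 80.9 and 22.2 CPM, and the imprinted zinc finger gene Plagl1 at 127 and 37.6 CPM. The secreted protease Htra3, the microfibril gene Mfap4 and the basement membrane collagen Col4a2 had ratios of 0.299, 0.292 and 0.316. The interferon-induced GTPase Iigp1 stood at 65.8 and 18.8 CPM (0.286), and Irf7, a transcription factor of the interferon response, at 57.8 and 17.9 CPM (0.310). Ambient RNA could give up to 27.1 CPM of Irf7 in the WT and 16.7 CPM in the KO library, the latter close to the KO value. Irf7 turned from a log2 ratio of -1.45 to 0.04 with a minimum of 2000 UMIs in both libraries.

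Lists of myogenic differentiation and of the cell cycle lay above the matched random lists, and stem cell genes below. Of 26 measured commitment and fusion genes, 20 were higher in the KO library (median log2 ratio 0.66, percentile 100), among them Myod1 (84.4 and 164 CPM), Mymx (79.8 and 157), Chrna1 (345 and 626) and Neb (133 and 269.5). Of 29 sarcomere genes, 25 were higher (median 0.55, percentile 100), with Tnnt2 at 198 and 581 CPM and Tnnc2 at 68.6 and 202 CPM. Of 26 stem and quiescence genes, 20 were lower (median -0.29, percentile 0), with Pax7 at 152 and 91.5 CPM, Myf5 at 170.1 and 90.1 CPM and the Notch target Hey1 at 42.7 and 19.3 CPM. All 27 S phase genes were higher (median 0.64), such as Mcm2 (10.3 and 24.2 CPM) and Pcna (56.7 and 100.1), as were 29 of 30 G2 and M phase genes (median 0.55), such as Top2a (159 and 304 CPM) and Cdk1 (62.8 and 117). Oxidative phosphorylation genes were higher in 27 of 33 cases (median 0.24, percentile 98.1), with Cycs at 259.98 and 437 CPM. Within the Pax7-led cluster alone, the S phase median was 0.81, the commitment median 0.40, the sarcomere median 0.32 and the stem median -0.22. Within the cycling cluster the S phase and G2 and M phase medians of 0.0569 and 0.0038 and the stem median of -0.0246 lay inside the range of the random lists, while the commitment and sarcomere medians were 0.32 and 0.47. Within the Myog-led cluster the S phase, commitment, sarcomere and stem medians were 0.38, -0.09, -0.35 and 0.0811.

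Interferon-stimulated genes, the antiviral genes switched on by interferon, were lower in the KO library in 42 of 48 cases in myogenic-like cells (median log2 ratio -0.66, percentile 0). Examples were Ifit3 at 35.1 and 8.51 CPM, Gbp7 at 41.4 and 11.0 CPM and Zbp1, a sensor of unusual nucleic acids, at 42.1 and 18.3 CPM. Nucleic acid sensing genes had a median of -0.25 (11 of 15 lower) and class I antigen presentation genes a median of -0.19 (10 of 14 lower), with B2m at 337 and 236 CPM. With a minimum of 2000 UMIs in both libraries these 2 medians were 0.13 and 0.34, and that of the interferon-stimulated genes was -0.17. The median depth of the myogenic-like cells was then 17120.5 UMIs in the WT and 4198 in the KO library. Of 31 immediate early and heat shock genes, 30 were lower (median -0.65, percentile 0, and -0.39 with that minimum), with Dnajb1 at 457 and 209 CPM, Ier2 at 361 and 183 CPM and Socs3 at 219 and 119 CPM. Of 21 imprinted genes, 18 were lower (median -0.37, percentile 0), among them Mest (1543 and 589.6 CPM), Peg10 (27.6 and 9.52), Igf2 (25.3 and 10.4) and Plagl1. TGF-beta response genes were lower in 15 of 22 cases (median -0.22) with Id3 at 1159 and 618 CPM, and 19 of 29 p53 targets were lower (median -0.18) with Gadd45g at 361 and 171 CPM.

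Collagen and matrix genes went both ways, 15 higher and 16 lower (median -0.14, 0.18 with a minimum of 2000 UMIs), with Col4a1 at 135 and 48.3 CPM and the matrix protein tenascin C (Tnc) at 30.8 and 67.4 CPM. Of 33 germline and early embryo genes only 6 had 20 UMIs over both libraries together, a filter that a gene can pass on its KO UMIs alone, so their median of 0.67 (0.12 over members with 5 UMIs) gives no direction for the list. The piRNA pathway helicase Tdrd9 stood at 0.447 and 21.7 CPM, the meiotic cohesin subunit Stag3 at 0.521 and 7.28 CPM, and Tex19.1 at 0 and 3.47 CPM. The heterochromatin machinery had a median of 0.13 (18 of 24 higher, percentile 84.5), with Resf1, Atf7ip and the maintenance DNA methyltransferase Dnmt1 (45.8 and 88.7 CPM) higher. All 8 measured class II antigen presentation genes were higher (median 0.67), with Cd74 at 101 and 193 CPM, and most of them lay under 2 times the level that ambient RNA could give, as did most genes of the inflammatory cytokine, complement and reparative macrophage lists (medians 0.22, 0.17 and 0.24). The inflammatory median was -0.54 over members with 100 UMIs.

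In mononuclear phagocyte-like cells the 12 lowest genes included AC160336.1, Plac8, Ly6c2 and 4 genes of the interferon-stimulated list, and the 12 highest included Fcrls, F13a1, Mrc1 and Gdf3. Plac8 and Ly6c2, which mark inflammatory monocytes, stood at 460.3 and 129.96 CPM (ratio 0.282 [0.273 to 0.292]) and at 244 and 93.7 CPM (0.383). The interferon-stimulated genes Isg15 (848 and 391 CPM), Ifit3 (295 and 126), Ifit3b (68.0 and 25.8) and Ifi44 (73.6 and 33.5), together with Isg20 and Phf11b, had ratios from 0.37997 to 0.462. AC160336.1 (0.0105), AW112010 (0.434), the stem cell antigen gene Ly6a (750.1 and 331 CPM) and the chemokine Ccl5 (141 and 68.1 CPM) completed the 12 lowest. Fcrls stood at 249.6 and 512 CPM (2.05 [2.0004 to 2.10]), the transglutaminase gene F13a1 at 139.9 and 289 CPM (2.06), the mannose receptor Mrc1 at 278 and 492 CPM (1.77) and Gdf3, a TGF-beta family ligand, at 34.3 and 78.0 CPM (2.28). The signalling inhibitors Socs3 (70.4 and 141 CPM) and Tnfaip3 (33.4 and 58.5), with Nxpe5 and the pseudogene Ubb-ps, had ratios from 1.74 to 2.003. Col1a1, Col1a2, Col3a1 and Fn1 were also among the 12 highest, and lay under 2 times the level that ambient RNA could give.

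Of 49 interferon-stimulated genes, 47 were lower in phagocyte-like cells (median log2 ratio -0.54, percentile 0), as were all 15 class I antigen presentation genes (median -0.29), with H2-T22 at 122 and 72.4 CPM and the immunoproteasome gene Psmb9 at 217 and 149 CPM. All 17 NF-kB feedback genes were higher (median 0.36, percentile 100), with Nfkb2 at 29.7 and 47.3 CPM and Nfkbiz at 86.2 and 129 CPM. Immediate early and heat shock genes were higher in 26 of 31 cases (median 0.26), with Klf4 at 145 and 242 CPM and Egr1 at 245 and 383 CPM. Reparative macrophage genes were higher in 21 of 29 cases (median 0.17), chemokines had a median of -0.17 (15 of 26 lower) with Ccl6 at 446 and 259 CPM and Cxcl9 at 91.7 and 49.5 CPM, and 29 of 33 oxidative phosphorylation genes were lower (median -0.10), with Cox5a at 557 and 467 CPM. Most of the collagen and matrix genes (median 0.33) lay under 2 times the ambient level, as did Col1a1 and other members of the TGF-beta response list (median 0.26). S phase and G2 and M phase genes had medians of 0.07 and 0.08. The median log2 ratio of all measured genes, against which these values stand, was 0.10 in this class and 0.16 in tenocyte-like cells. It was 0.09 in both endothelial-like and dendritic-like cells.

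Clusters of phagocyte-like cells built without the interferon-stimulated and named genes (3321 WT and 3131 KO cells), a setting chosen after the data were seen, differed in their shares. A cluster led by Ly6c2 and Plac8 held 4.19% of the WT and 0.926% of the KO cells (ratio 0.221 [0.143 to 0.332]), against 5.35% and 2.05% (0.383 [0.277 to 0.521]) with all genes used, and one led by Ifit2 and Slfn1 15.4% and 6.71% (0.437 [0.370 to 0.514]). A cluster led by class II antigen presentation genes and Cx3cr1 held 21.5% and 29.4% (1.37 [1.24 to 1.51]), and one led by Mmp12 and Il7r 10.0% and 14.5% (1.45 [1.26 to 1.68]). A cluster led by Cbr2, Ccl8, F13a1 and Mrc1 held 10.8% and 13.03% (1.202). One led by the haemoglobin gene Hbb-bs, with Ms4a7 and Apoe also among its leading genes, held 24.4% and 21.2% (0.867). One led by Gpnmb and Spp1 held 10.6% and 11.7% (1.10) and a cycling one 3.07% and 2.56% (0.832).

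Fibro-adipogenic or fibroblast-like cells of the KO library held more RNA of the cell cycle lists and less of the interferon-stimulated, class I antigen presentation and complement lists. The 5 highest genes were AA465934, the histone genes H2ac4, H1f5 (74.3 and 273 CPM) and Hist1h2ap (118 and 414), and Tnc at 387 and 1221 CPM (ratio 3.15 [3.07 to 3.24]). The 5 lowest were AC160336.1 (0.0115), haptoglobin (Hp, 112 and 14.3 CPM, 0.128), the matrix protease Mmp3 (63.5 and 9.86 CPM, 0.155), Apod (1416 and 300.2 CPM, 0.212) and Ifit3 (148 and 34.9 CPM, 0.236). All 27 S phase genes (median log2 ratio 0.70) and all 30 G2 and M phase genes (0.71) were higher, such as Top2a at 58.4 and 152 CPM, and a cycling cluster held 8.16% and 25.3% of the class (3.10 [2.33 to 4.18]). Of 49 interferon-stimulated genes 48 were lower (median -0.79), and so were all 15 class I antigen presentation genes (-0.75). Complement genes had a median of -0.82 with C3 at 202 and 73.5 CPM and Cfb at 34.0 and 12.9 CPM. The 6 of 14 that were higher, such as C1qa, lay under 2 times the ambient level. Collagen and matrix genes were higher in 23 of 32 cases (median 0.28), with Col12a1 at 177 and 397 CPM. At a resolution of 2 a cluster led by Tnc, Lrrc15 and Cthrc1 held 8.03% and 30.6% of the class (3.81 [2.87 to 5.12]), where Tnc is also among the genes that differed. The contractile actin Acta2 and the ligand Tgfb2 of the TGF-beta list stood at 414 and 978 CPM and at 54.4 and 124 CPM. The signals Il33 (204 and 69.0 CPM) and Il6 (83.9 and 35.7) and the chemokines Cxcl13 (46.8 and 2.95), Cxcl14 (885 and 256) and Cxcl9 (344 and 109) were lower, while the chemokine list as a whole had a median of -0.09, which became 0.51 with a minimum of 2000 UMIs. A cluster led by Apod and Sfrp5 held 4.27% and 1.253% of the class (0.293 [0.129 to 0.609]).

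In endothelial-like cells Igfbp5, a binding protein of insulin-like growth factors, stood at 9.37 and 70.5 CPM (ratio 7.52 [5.83 to 9.83], from 52 WT and 50 KO cells, with 22.3% of the KO UMIs in 1 cell) and the glycoprotein hormone Stc1 at 16.1 and 51.8 CPM (3.21). Irf7 (412 and 134 CPM), Ifit3 (234 and 82.4) and Cxcl9 (357 and 136) were lower, and 46 of 49 interferon-stimulated genes were lower (median log2 ratio -0.56). All 17 NF-kB feedback genes were higher (0.39), as were 17 of 21 angiogenic endothelial genes (0.38), with the leukocyte adhesion genes Sele at 305 and 547 CPM and Selp at 753 and 1179 CPM. Cd74, H2-Aa and Ccl8 were among the 5 highest and lay under 2 times the ambient level. With doublets kept, the log2 ratios of Cd74 and H2-Aa were -0.32 and -0.30 in place of 1.34 and 1.15. The lymphatic chemokine Ccl21a stood at 151 and 3.25 CPM, with 76.1% of its WT and 91.7% of its KO UMIs in 1 cell each, and its log2 ratio of -4.24 turned to 1.83 with a minimum of 2000 UMIs.

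In tenocyte-like cells cell cycle genes were higher in the KO library, with a median log2 ratio of 0.96 for S phase genes (25 of 26 higher) and 1.28 for G2 and M phase genes (all 19 higher, 0.68 with a pseudocount of 20). Most of the latter lay under 2 times the ambient level. Pclaf, a partner of the replication clamp, stood at 1.40 and 52.8 CPM, with 35.8% of its KO UMIs in 1 cell, and the microtubule gene Stmn1 at 14.0 and 83.2 CPM. AA465934 stood at 8.40 and 63.4 CPM and Hist1h2ap, under 2 times the ambient level, at 4.90 and 79.7 CPM. Lcn2 (60.2 and 6.16 CPM), Clu (83.3 and 11.0), Chchd10 (67.9 and 9.24) and AC160336.1 were lower, the cytokine Il11 stood at 162 CPM in 6 WT cells and 0.440 CPM in the KO library, and Ccl5 had 89.6% of its KO UMIs in 1 cell. The interferon-stimulated list, also mostly under 2 times the ambient level, had a median of -0.02, which turned to 0.15 with a minimum of 2000 UMIs.

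Mural-like cells were spread unevenly over their 3 clusters, with 36, 51 and 35 WT and 71, 23 and 31 KO cells. Their G2 and M phase genes were all higher in the KO library (30 genes, median log2 ratio 0.86) and so were 29 of 31 collagen and matrix genes (0.86), of which Col1a1 and Dcn lay under 2 times the ambient level. The chemokine Ccl7 stood at 29.2 and 134 CPM, and Clu (191 and 31.6), Rbp7 (177 and 47.4), Stmn2 (143 and 38.0) and Cxcl9 were lower. The KO cell with the most UMIs of a gene held 72.8% of those of Cxcl14, 73.0% of those of Dcn and 39.7% of those of Hmox1, and need not be the same cell for each.

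In dendritic-like cells Lmna, the gene of nuclear lamin A, stood at 29.4 and 83.6 CPM, Ahnak at 173 and 408 CPM and Serpinb6b at 24.1 and 67.2 CPM. Ly6c2 (364 and 110.4 CPM), Slfn1 (68.4 and 20.7), Ifit3 (145 and 50.9), Ly6a (607 and 251) and AC160336.1 were lower, with 45 of 49 interferon-stimulated genes lower (median log2 ratio -0.47). Ccl8 lay under 2 times the ambient level, and 56.9% of the KO UMIs of Cxcl3 came from 1 cell. In cluster 3 the growth factor Areg stood at 9.67 and 67.6 CPM (ratio 6.995 [5.37 to 9.25]) and the neutrophil-attracting chemokine Cxcl1 at 274 and 739 CPM (2.698), followed by F13a1, Fcrls and Pdpn (2.73, 2.69 and 2.55). Ly6c2 (379 and 78.4 CPM), Plac8 (265 and 73.5), Ly6a (441 and 135), Ccl5 (100.3 and 32.9) and AC160336.1 were the lowest. Interferon-stimulated genes were lower in 47 of 49 cases (median -0.54), and hypoxia and glycolysis genes higher in 21 of 23 (0.32), with the glucose transporter Slc2a1 at 32.3 and 52.9 CPM.

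**Figure D5:**
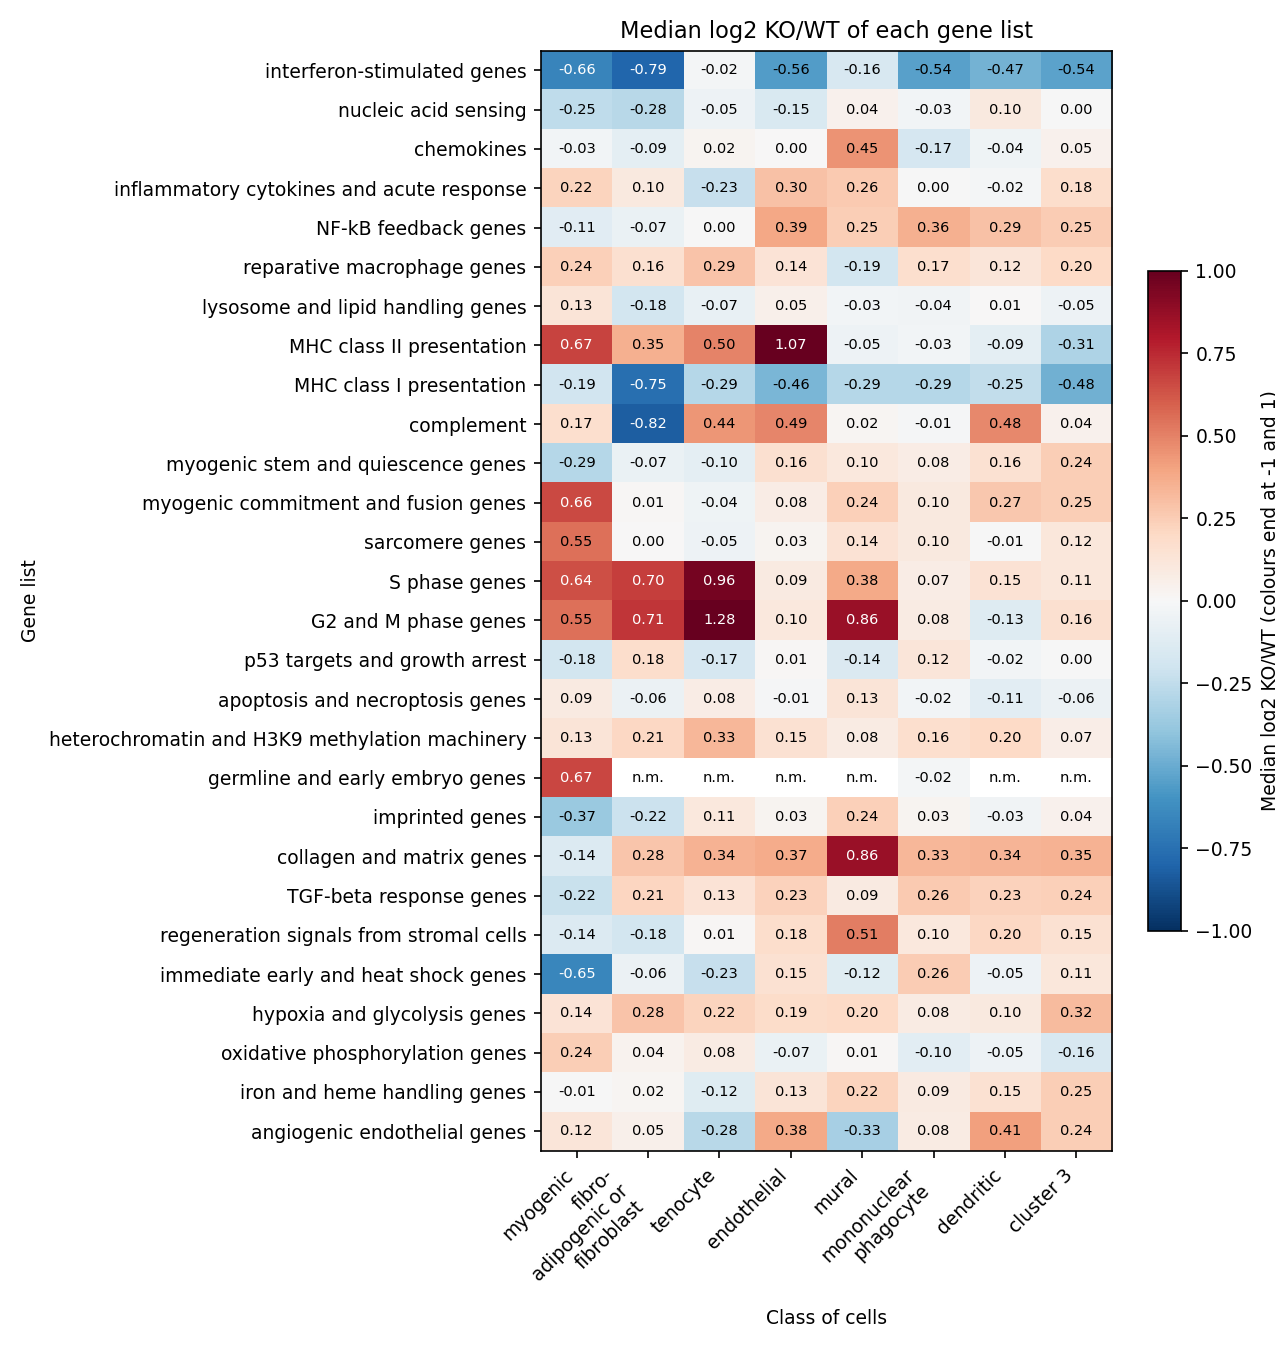
Median log2 KO/WT ratio (colour and printed value) of the 28 gene lists fixed before the data were examined (vertical axis) in 8 groups of cells (horizontal axis), with n.m. where fewer than 5 members had 20 UMIs. The interferon-stimulated list ranges from -0.79 in fibro-adipogenic or fibroblast-like cells to -0.02 in tenocyte-like cells, and the immediate early list has opposite signs in myogenic-like (-0.65) and phagocyte-like (0.26) cells.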

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

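The tests of barcode read errors and of free RNA in the fibro-adipogenic or fibroblast-like barcodes were chosen only after the results were seen. Of the KO barcodes with at least 500 UMIs and 300 genes that were left by the mitochondrial filter and the removal of doublets, 61.6% [60.8 to 62.3] (9392 of 15257) lay below that library's UMI minimum and entered the comparisons only where a lower minimum was tried, against 25.7% [24.7 to 26.6] (2175 of 8476) in the WT library. The KO barcodes held 2596 fibro-adipogenic or fibroblast-like, 2270 phagocyte-like, 1549 endothelial-like and 702 myogenic-like profiles at a median depth of 1985 UMIs. Read errors in the barcodes of deep cells may make such copies, but only 0.405% of them differed by 1 base from a called barcode, which argues against this source. Free RNA could make up at most 30.5% of their RNA in the median class. This argues against free RNA as the larger part only for the named classes measured, since barcodes in unnamed clusters were not covered. The limit was 48.6% in tenocyte-like and 43.3% in mural-like barcodes, so free RNA could still be a large part there. In the fibro-adipogenic or fibroblast-like barcodes the limit for free RNA was 51.7%, which leaves it open there. Loss of cytoplasm also stays open, since Malat1, a nuclear RNA, took 1.31 times its share in called cells in the median class. That lies between the values named for and against it beforehand. By class the KO ratio ran from 0.950 in tenocyte-like to 1.64 [1.62 to 1.66] in myogenic-like barcodes. The last is above the value named for loss of cytoplasm, and the first below that named against it. A difference between the genotypes in small or fragile cells could not be tested with 1 library per group.

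The remaining results had opposite signs in myogenic-like and phagocyte-like cells, and the difference between the classes was not tested. Immediate early and heat shock genes had a median log2 KO/WT ratio of -0.65 in myogenic-like and 0.26 in phagocyte-like cells. TGF-beta response genes had medians of -0.22 and 0.26, the latter in part on genes under 2 times the ambient level, such as Col1a1. Collagen and matrix genes had medians of -0.14 and 0.33, the latter mostly on such genes, and the former turned to 0.18 with a minimum of 2000 UMIs and to 0.12 with each cell weighted equally. Oxidative phosphorylation genes had medians of 0.24 and -0.10.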

How the results depend on the processing

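The higher of the 2 UMI minimums in both libraries, clusters built without interferon-stimulated and named genes, the largest myogenic-like cluster alone, and the minimum of 2000 UMIs for the myogenic states were chosen only after the data were seen, and the other alternatives before. No paired analysis was possible because each group had 1 library. Values without a test were counted as moved when they left the counting interval, or for lists when they moved by more than the spread of the random lists allows. All 10 alternative values of the Setdb1 level stayed within the interval. Of 99 values for class shares 15 moved and 2 reversed, of 36 for myogenic states 3 moved, of 37 for clusters within classes 7 moved, of 652 for single genes 129 moved and 4 reversed, and of 1897 for gene lists 225 moved and 32 reversed. Clusters with fewer than 5 of 10 leading genes shared gave no value. Precision is limited by cell number in the tenocyte-like and mural-like classes, with 83 and 122 WT cells, and by depth in genes with few UMIs. The following are log2 KO/WT values, and the cause was not tested. Where a result has a value outside brackets, the brackets after it hold its main value, given where it is first named. Where brackets hold the only value of a result, it is the value under the alternative. In brackets with a value marked main, the other value is that of the alternative. A reversed value had the opposite sign under the main settings.

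With the higher of the 2 UMI minimums in both libraries the myogenic-like share stood at -0.79 (-0.72). With a minimum of 2000 UMIs it reversed to 0.0779, where the interval of the ratio held 1, and the unnamed share reversed to -0.0385 (0.69). The shares of fibro-adipogenic or fibroblast-like (1.07, main 0.19), tenocyte-like (1.43, main 0.56), phagocyte-like (-0.36, main -0.01) and dendritic-like cells (-0.89, main -0.54) moved. At this minimum the median depth of myogenic-like cells was 17120.5 UMIs in the WT and 4198 in the KO library. In myogenic-like cells interferon-stimulated genes then stood at -0.17 (-0.66), sarcomere genes at 0.37 (0.55), G2 and M phase genes at 0.37 (0.55) and immediate early genes at -0.39 (-0.65), while Irf7 reversed to 0.0393, nucleic acid sensing to 0.13, MHC class I to 0.34 and collagen to 0.18. The share of myogenic-like cells with a UMI of Mki67 stood at 0.28 (1.08). Also reversed were Ccl21a in endothelial-like cells (1.83, main -4.24), chemokines (0.51), lysosome genes (0.20) and stem genes (0.0134) in fibro-adipogenic or fibroblast-like cells, reparative (0.51) and commitment genes (-0.0339) in mural-like cells, and apoptosis genes in phagocyte-like cells (0.0033). In tenocyte-like cells the interferon (0.15), inflammatory (0.0434), lysosome (0.18), MHC class I (0.0740), p53 (0.0740) and iron (0.0465) lists reversed. With at least 500 UMIs the shares were -0.41 for myogenic-like, 1.15 for fibro-adipogenic or fibroblast-like, -0.30 for endothelial-like (-0.08), -0.35 for phagocyte-like and -0.93 for dendritic-like cells and 0.49 for the unnamed clusters.

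The unnamed share was 0.39 at a resolution of 0.5, 0.98 at 2, 0.93 without the interferon-stimulated and named genes and 0.37 with up to 25% mitochondrial UMIs, where the phagocyte-like share was 0.0895. The phagocyte-like cluster led by Ccl8 and F13a1 stood at 0.35 at a resolution of 0.5 and at 0.27 without those genes (0.60), and the Ly6c2-led one at -2.18 without them (-1.39). At a resolution of 2 the Pax7-led myogenic-like cluster stood at -2.03 (-0.44) beside a Gsta4-led one at 0.73, 2 phagocyte-like clusters at 0.38 (0.57) and -1.08 (-0.77), and the main fibro-adipogenic or fibroblast-like cluster at -1.05 (-0.26). Thinned to 500 UMIs, Myf5 stood at -1.59 (-0.84) and Mki67 at 0.44.

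With each cell weighted equally, the myogenic-like medians were -0.56 for interferon-stimulated, 0.76 for sarcomere, 0.81 for S phase (0.64), 0.73 for G2 and M phase and -0.43 for immediate early genes. Collagen reversed to 0.12, and in tenocyte-like cells interferon-stimulated (0.0228), lysosome (0.23) and stem genes (0.0684) reversed. In the largest myogenic-like cluster alone commitment genes stood at 0.40 (0.66), sarcomere at 0.32, S phase at 0.81 and immediate early genes at -0.46. A pseudocount of 20 CPM, which shrinks low genes by construction, gave -0.33 for interferon-stimulated, 0.48 for commitment, 0.42 for sarcomere, 0.48 for S phase and 0.43 for G2 and M phase genes. The myogenic-like interferon median was -0.77 without mitochondrial and ribosomal totals, and the phagocyte-like one -0.64 with median-ratio scaling (-0.54).

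With doublets kept, the myogenic-like interferon median was -0.48, and Cd74 (-0.32) and H2-Aa (-0.30) in endothelial-like cells, MHC class II in fibro-adipogenic or fibroblast-like (-0.15), tenocyte-like (-0.0568) and endothelial-like cells (-0.27), and reparative (0.0647) and angiogenic genes (0.0892) in mural-like cells reversed. With 5% ambient RNA subtracted, inflammatory genes in myogenic-like (-0.14), interferon-stimulated genes in tenocyte-like (0.10) and angiogenic genes in dendritic-like cells (-0.0233) reversed. Over members with 100 UMIs, inflammatory genes in myogenic-like (-0.54), complement (-0.25) and stem genes (0.0314) in tenocyte-like, and G2 and M phase genes in cluster 3 (-0.0753) reversed, as did commitment genes in dendritic-like cells over members with 5 UMIs (-0.0084).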

Other observations

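The test of a loss of Setdb1 in myogenic cells alone was chosen only after the result was seen. Beside AC160336.1, 8 genes lay beyond 0.5 on the log2 scale in the same direction in all 8 groups of cells. Irf7, the interferon transcription factor, had a median log2 KO/WT ratio of -1.21 (-1.72 to -0.89), with 639 and 337 CPM in phagocyte-like cells and a value of 0.0393 in myogenic-like cells with a minimum of 2000 UMIs, and the pseudogene Ndufs5-ps one of -1.31. The collagen triple helix repeat gene Cthrc1 (median 0.66) and the Fc receptor-like gene Fcrls (0.97) were higher, but lay under 2 times the ambient level in 6 and 5 of the 8 groups, as Irf7 did in 1. Also higher were the transcripts AA465934 (1.62), Gm37706 (1.62), Gm10095 (1.06) and Ubb-ps (0.57).

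The medians of further gene lists are given by class without their percentiles, so some may lie inside the range of the random lists. Differences between classes were not tested. NF-kB feedback genes, which were higher in phagocyte-like and endothelial-like cells, were also higher in all 17 cases in cluster 3 (median log2 ratio 0.25) and in 15 of 17 in dendritic-like cells (0.29), while myogenic-like cells had a median of -0.11 (11 of 17 lower). Hypoxia and glycolysis genes were higher in 21 of 23 cases in fibro-adipogenic or fibroblast-like cells (0.28), with the lactate exporter Slc16a3 at 13.5 and 25.9 CPM. In myogenic-like cells this list had a median of 0.14 (18 of 23 higher), with lactate dehydrogenase Ldha at 308 and 537 CPM but hexokinase Hk2 at 62.5 and 27.1 CPM. Lysosome and lipid handling genes had medians of 0.13 in myogenic-like and -0.18 in fibro-adipogenic or fibroblast-like cells (0.20 with a minimum of 2000 UMIs), and iron and heme genes -0.01 in myogenic-like and 0.25 in cluster 3. Apoptosis and necroptosis genes had medians of 0.09 in myogenic-like and -0.02 in phagocyte-like cells (0.0033 with a minimum of 2000 UMIs), and signals from stromal cells -0.14 and 0.10. Angiogenic genes had a median of 0.12 in myogenic-like cells, with the growth factor Pgf at 26.4 and 6.83 CPM, and of -0.33 in mural-like cells (0.0892 with doublets kept). Chemokines in myogenic-like cells had a median of -0.03 (1.254 with a minimum of 2000 UMIs), with Ccl2 at 107 and 42.9 CPM and Ccl11 at 19.7 and 3.81 CPM. In myogenic-like cells most genes of the chemokine, angiogenic and lysosome lists lay under 2 times the ambient level.

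AC160336.1 was lower in the KO library in all 8 groups of cells, with a median log2 ratio of -5.16 (-5.49 to -4.22). A loss of Setdb1 in myogenic cells alone is argued against as the direct source, since the ratio in phagocyte-like cells was 0.0105 [0.00889 to 0.0123]. Reads counted for a near-identical copy instead are argued against too, since the sum over AC160336.1 and the 139 genes sharing sequence with it had a ratio of 0.394 [0.385 to 0.404]. The sum cannot show reads that match several copies alike, should the counting have dropped them, and its settings are not given. Such a loss of reads therefore stays open. A strain or haplotype difference between the animals may be the source and stays open: 4.17% of the measured genes within 5 Mb (1 of 24) lay apart in every class, against 0.0909% elsewhere (7 of 7697), but that share rests on 1 gene, Ubb-ps, which was higher in the KO library.

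Interferon-stimulated genes were lower in the KO library in most classes, though in myogenic-like cells their median of -0.66 stood at -0.17 with a minimum of 2000 UMIs, where Irf7 stood at 0.0393. The list's median within the 8 phagocyte-like clusters built without these genes was -0.43 (-1.001 to 0.02). It lay under -0.25 in 6 of the 8, and the others were the Ifit2-led and Gpnmb-led clusters, at 0.02 and -0.21. A change in the shares of these 8 clusters alone is argued against as the whole source. Fewer interferon-high cells stay open as a source, since clusters built without these genes can mix interferon-high and interferon-low cells. In myogenic-like cells above the main UMI minimums, the median was -0.78 with free RNA subtracted from both libraries at its highest possible share. That share was larger in the KO library (9.98%) than in the WT library (6.99%), so more was taken from the KO library. The value therefore cannot tell whether free RNA from other cells gives part of the difference, which stays open. A difference between the animals or preparations, with or without a part of Setdb1, could give the same pattern and cannot be tested with 1 library per group.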
